A study of Homo sapiens with 6 samples.

How the data were processed

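RNA sequencing of HuCCT1, an established human cholangiocarcinoma cell line, was analysed in 6 libraries, 3 labelled siC1QBP (cells given a small interfering RNA against C1QBP) and 3 labelled siNC (the control siRNA). Per the labels' protocols, total RNA was purified on RNeasy columns and made into libraries with a strand-marking NEBNext Ultra Directional kit. The authors deposited raw counts per gene, whole numbers with no normalization, for 58735 genes in each library. The submitters' processing notes name the genome build hg38; the aligner, the counting program and its strand setting are not given in the sources used here. Gene identifiers and coordinates of all 58735 genes matched GENCODE release 29. Without a stated strand setting, reads of overlapping and antisense genes may have been assigned to either partner, and reads of near-identical copies such as U2AF1 and U2AF1L5 may have been split between them. Every row carried a gene name, so no counts were set aside.

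Total counts ranged from 17122252 to 20416243 per library. A gene with no count in a library could therefore hold up to 0.147 to 0.175 CPM (counts scaled to the library total), the level of 3 counts; this limit covers counting error only. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Before replicates were averaged, each pair of libraries was compared by a chi-square test over genes with at least 20 counts in the pair. The statistic per degree of freedom was 2.09 to 6.77 for the 6 pairs within a group and 7.12 to 18.0 for the 9 pairs between groups, so no pair looked like one library deposited more than once.

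Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default low-count filter (filterByExpr), treatment as the only term, and Benjamini-Hochberg adjustment over the 15530 genes that passed the filter. Genes with an adjusted p under 0.05 were called. Fold changes are siC1QBP over siNC on the log2 scale with their standard error (SE), and CPM are on TMM-scaled library sizes. The SE of a median over genes, or of a difference of such medians, is computed across the genes as if independent. It leaves out differences between libraries that the genes share. Confidence intervals of single fold changes use the normal approximation. Single values per library were compared with a two-sided exact permutation test, whose smallest possible p for 3 against 3 is 0.1. Counts were also simulated for 15530 genes with the means and library sizes of these samples. Changes of each size were planted in 50 genes with a mean of at least 5 CPM. The test called 60% of genes changed 1.25-fold, 96% of those changed 1.5-fold and 100% of those changed 2-fold, and 4.49% of its calls were false. Recovery in fainter genes was not measured. Counts were drawn independently for each gene and library, so the 4.49% leaves out differences between libraries that genes share.

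A set of 44 gene lists with 1122 entries was written before the data were examined, of which 1121 entries matched a gene. The 38 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1; log2 CPM with a prior count of 2; preset correlation between genes of 0.01; two-sided), adjusted over the 38 lists. Camera with a correlation estimated per list and fry, which asks whether a list's genes move one way on balance, were run beside it. The genes named were set by a rule written before the data were examined. It takes C1QBP, PAICS, PTK2 and MYC. It adds the 8 largest rises and 8 largest falls and the 4 smallest p-values each way, among called protein-coding genes with at least 5 CPM in the higher group and no overlap between groups. From each list it takes up to 3 called members with the smallest p and 1 called member in the opposite direction, or, with no call, the 2 members with the highest CPM. Of the genes so chosen, 2 are not reported here.

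The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, other scalings, looser and stricter low-count filters, protein-coding genes only, mitochondrially encoded genes left out, each library left out, the replicate number as a block, and an adjusted p under 0.01. Removing each library's trend with transcript length and GC content, and thinning counts to the smallest library, were added after seeing the data. For words in 3' UTRs, 7-base words were scored in 10517 protein-coding genes with at least 5 CPM and a 3' UTR of at least 50 bases, taken from the annotated transcript with the longest 3' UTR, after regression on length, GC content, base composition and expression, against 100 permutations of genes. A scan with the 3' UTR of the principal transcript came first, and the longest 3' UTR was adopted after its result had been seen; both are given. Transcript sequences came from GENCODE release 29. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.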

Results

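The series compared HuCCT1 cholangiocarcinoma cells given an siRNA against C1QBP with cells given a control siRNA, in 3 libraries each. Its title concerns a feedback loop between C1QBP, PAICS, FAK and c-Myc in proliferation. Raw counts per gene totalled 17122252 to 18847340 in the siC1QBP libraries and 18313264 to 20416243 in the siNC libraries.

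C1QBP, a protein mainly of the mitochondrial matrix, fell to 32.7% of its control level (95% interval 30.6% to 34.9%), and MYC and PAICS fell far less. Nuclear genes for the respiratory chain, both ribosomes, glycolysis and the cell cycle were lower in siC1QBP cells, with list medians from -0.23 to -0.11 on the log2 scale. These list calls were made with a preset correlation between genes and were lost when the test estimated it per list. The estimate was 0.513 for cytosolic ribosomal proteins but 0.00513 for glycolysis, below the preset 0.01. The loss therefore does not by itself show correlated genes. Of 26 tested genes of the mitochondrial genome 12 rose and 2 fell. The immediate early genes FOS and EGR1, the cytokine gene TNFSF15 and the extracellular matrix genes TGFBI, FN1 and COL1A1 rose.

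In total, 2222 of 15530 tested genes passed an adjusted p of 0.05 (edgeR), 1005 of them higher and 1217 lower. Among these, the median absolute log2 fold change was 0.29 and 93 genes changed at least 2-fold, 84 higher and 9 lower. The count of 2222 became 1090 without siNC replicate 2 and 1193 without siNC replicate 3. The count of 93 became 20 with DESeq2, 7 with a filter of at least 10 CPM, and 58, 51 and 53 without siC1QBP replicate 2, siNC replicate 2 and siNC replicate 3. With library size as the only scaling, 1253 genes were higher and 908 lower, so the split between rises and falls moved with the scaling.

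The siRNA target, C1QBP (ENSG00000108561; hg38 chromosome 17, 5432777 to 5448830, minus strand), stood at 58.9 ± 1.19 CPM in siC1QBP and 180 ± 4.94 CPM in siNC libraries (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The siC1QBP libraries ranged from 57.6 to 60.0 CPM and the siNC libraries from 175 to 185 CPM. The log2 fold change was -1.61 (SE 0.05; edgeR adjusted p = 1.39e-12).

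MYC (ENSG00000136997; chromosome 8, 127735434 to 127741434, plus strand), a growth-promoting transcription factor, fell by 0.23 on the log2 scale (SE 0.06; edgeR adjusted p = 0.0101), from 86.1 ± 0.583 to 73.2 ± 5.11 CPM (SD). PAICS (ENSG00000128050; chromosome 4, 56435741 to 56464579, plus strand), an enzyme of de novo purine synthesis, fell by 0.14 (SE 0.04; edgeR adjusted p = 0.0384), from 237 ± 4.07 to 216 ± 6.19 CPM. PTK2 (ENSG00000169398; chromosome 8, 140657900 to 141002216, minus strand), which encodes FAK, did not pass, with a log2 fold change of 0.07 (95% interval -0.02 to 0.16; edgeR adjusted p = 0.323) and 138 ± 3.95 against 131 ± 0.661 CPM. The MYC call was lost without siNC replicate 3 (edgeR adjusted p = 0.0502). The PAICS call was lost without siC1QBP replicate 2 (0.139) or 3 (0.0800), without siNC replicate 1 (0.0886), 2 (0.0859) or 3 (0.139), and with library size as the only scaling (0.0787; edgeR adjusted p throughout).

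**Figure D1:**
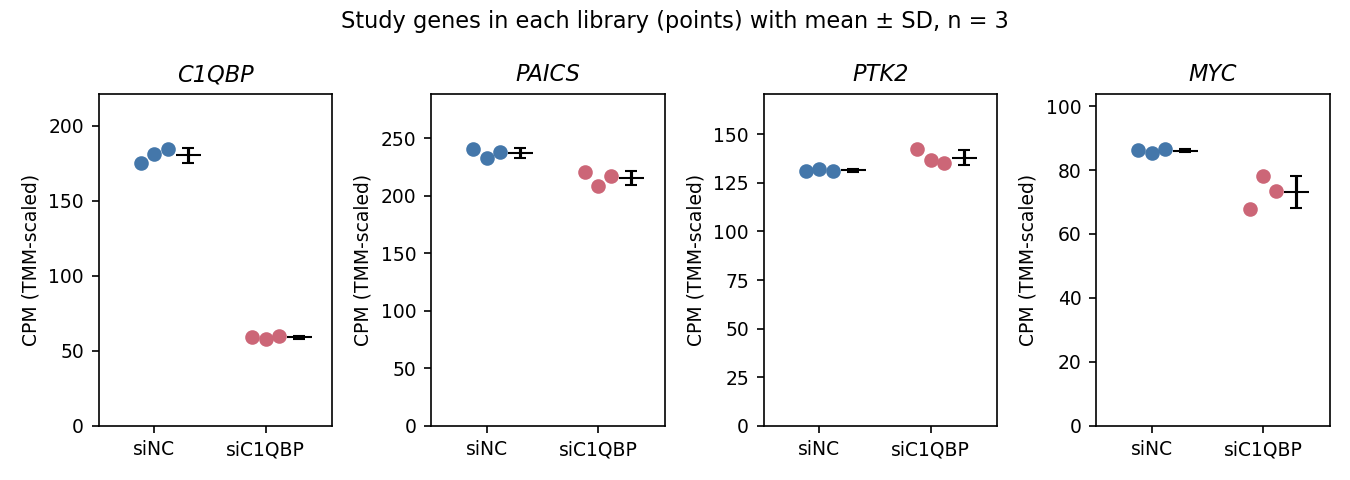
Expression of C1QBP, PAICS, PTK2 and MYC in TMM-scaled CPM (vertical axes from 0) in the siNC and siC1QBP libraries; points are libraries and the bars beside them are the mean ± SD (n = 3). C1QBP lies between 57.6 and 60.0 CPM in siC1QBP and between 175 and 185 CPM in siNC libraries, while the groups of the other genes lie close together.

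Under the naming rule, the largest rises were FOS (log2 fold change 1.46, SE 0.16), TNFSF15 (1.33, SE 0.08), the gastric-type mucin MUC6 (1.22, SE 0.15), EGR1 (1.18, SE 0.06), the Wnt inhibitor NKD1 (1.16, SE 0.13), U2AF1L5, AANAT (1.07, SE 0.20) and the retinol-binding protein RBP5 (0.92, SE 0.12). EGR1 went from 26.4 ± 0.544 to 60.1 ± 1.07 CPM and TNFSF15 from 16.5 ± 0.442 to 41.4 ± 3.03 CPM (SD, n = 3; edgeR adjusted p = 2.36e-09 and 1.59e-08). The rises with the smallest p also included TPM4, an actin-binding tropomyosin, at 502 ± 12.6 against 278 ± 4.06 CPM (log2 fold change 0.85), and PTGS2, the inducible cyclooxygenase, at 115 ± 4.72 against 62.1 ± 1.95 CPM (0.89). U2AF1L5 (1.15, SE 0.27) is a near-identical copy of U2AF1 and its value is uncertain; its call was lost without siC1QBP replicate 3 (edgeR adjusted p = 0.0630) or siNC replicate 2 (0.0578), and with DESeq2.

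After C1QBP, the largest falls were SNRPB2, a protein of the U2 spliceosomal particle, from 61.6 ± 2.39 to 23.9 ± 1.84 CPM (log2 fold change -1.37, SE 0.07), and TMEM238 (-1.10, SE 0.10). They were followed by the mitochondrial nuclease ENDOG (-0.99, SE 0.15), the transcriptional repressor HES4 (-0.85, SE 0.10), the mitochondrial RNA-binding protein SLIRP (-0.84, SE 0.08), the ATP synthase subunit ATP5MD (-0.82, SE 0.09) and the glycosyltransferase MGAT2 (-0.78, SE 0.19). MGAT2 lost its call without siNC replicate 2 (edgeR adjusted p = 0.0775). TNFAIP2 (-0.53, SE 0.04) and casein kinase CSNK1A1 (-0.53, SE 0.04) were the other falls with the smallest p. The 3' UTRs of TPM4, PTGS2, NOLC1, HIST1H2BD, SESN2 and PPARA hold TCGGAGA or CGGAGAA, words tied to higher fold changes across genes. Those of SNRPB2, CSNK1A1, PAICS, PTK2, NKD1, HK2, PGK1, EGLN1, UQCRB, RPS20, MCM2, MRPL17, DUSP6, SOD2, CLDN1, CDKN2B, SHMT1 and TOMM22 hold ATTATCC or TTATCCA. These words were tied to lower fold changes only after the regression on length, GC content, base composition and expression. Without it, genes with either word had a median of -0.008 against -0.021 for the others. Of the genes just named, NKD1, SOD2, CLDN1, CDKN2B and TOMM22 rose.

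**Figure D2:**
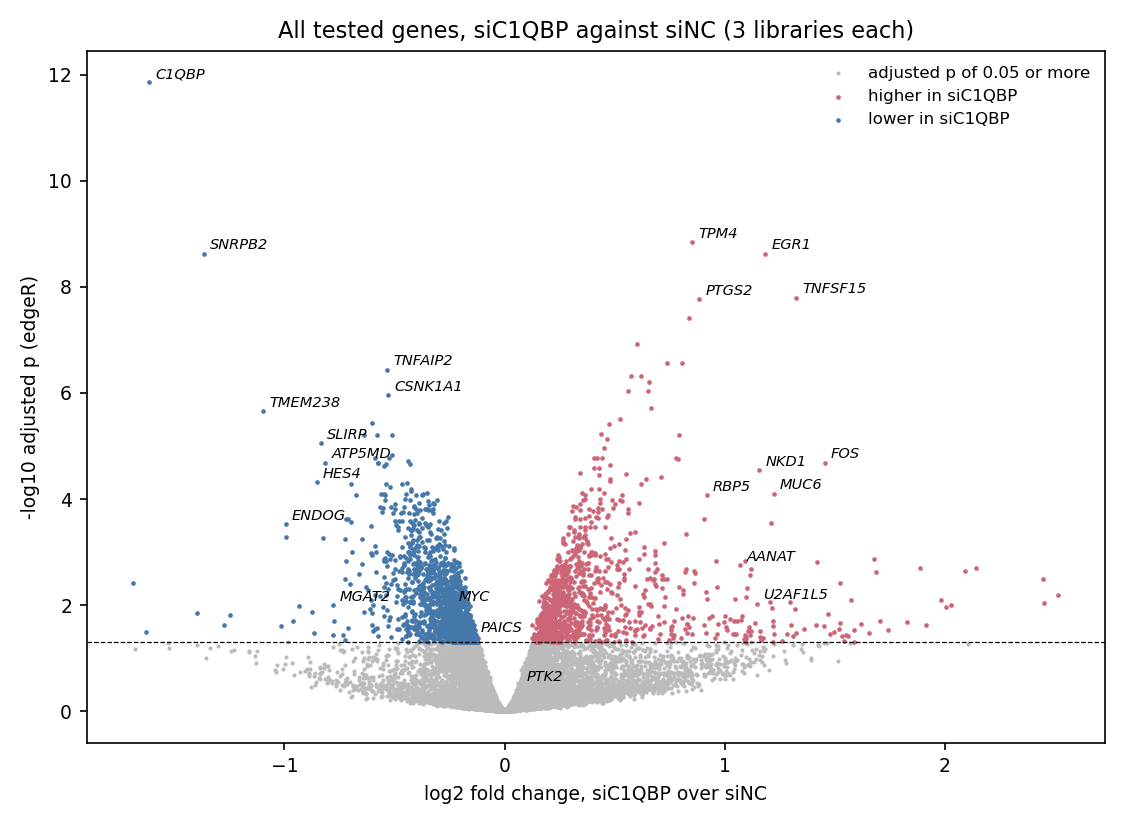
Log2 fold change of each of the 15530 tested genes, siC1QBP over siNC (horizontal axis), against -log10 of the edgeR adjusted p (vertical axis); red points are the 1005 genes called higher, blue the 1217 called lower, and the dashed line marks an adjusted p of 0.05. C1QBP lies at -1.61, apart from the other labelled genes, and PTK2 lies below the line.

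Several library-wide measures differed between the groups alongside these genes. The siC1QBP libraries had a count in 25187 ± 278 genes against 23614 ± 223 (SD, n = 3; exact permutation p = 0.1) and 4.43% ± 0.325 against 3.75% ± 0.119 of counts in mitochondrially encoded genes (exact permutation p = 0.1). Fold changes also followed transcript length. Of the 3105 genes with the shortest transcripts (median 966 bases) 97 rose and 418 fell, and of the 3105 with the longest (median 6817 bases) 392 rose and 98 fell. Replicate 1 of siC1QBP stood apart from replicates 2 and 3, with a chi-square per degree of freedom of 6.66 and 6.77 against 2.09 between those. Replicate 1 of siNC also stood apart, though less, with 3.67 and 3.40 against 2.13 between siNC replicates 2 and 3. Without siC1QBP replicate 1, 2607 genes passed (1134 higher, 1473 lower), and without siNC replicate 1, 1979 passed (845 higher, 1134 lower).

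Of 38 gene lists tested against all other genes, camera with a preset correlation called 12 lower and 5 higher. With a correlation estimated per list it called 0 (lowest adjusted p = 0.156, with 9 lists under an unadjusted p of 0.05), and fry called 24, of which 14 were among the 17.

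Cytosolic ribosomal protein genes, with a median transcript of 1010.5 bases, were lower as a list (median log2 fold change -0.17; camera adjusted p = 3.95e-10). The adjusted p was 0.383 with an estimated correlation and 0.0589 by fry. Of 78 members, 35 fell, 1 rose and 42 did not pass; adjusted over the list alone, 50 fell and 1 rose. RPS27A fell by 0.41 (SE 0.05), RPL24 by 0.36 (SE 0.05) and RPS20 by 0.35 (SE 0.05). RPL28 rose (0.15), a call lost without siC1QBP replicate 2 or 3 or siNC replicate 1 or 3 (edgeR adjusted p up to 0.104). Without siC1QBP replicate 1, the list's median was -0.11, with 41 members lower and 2 higher. The number lower was 19 without siNC replicate 2 and 21 without siNC replicate 3.

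Mitochondrial ribosome genes were lower too (median -0.17; camera adjusted p = 2.70e-09, and adjusted p = 0.236 with an estimated correlation). Of 78 members, 25 fell, 1 rose and 52 did not pass, and 40 fell and 1 rose adjusted over the list alone. Without siNC replicate 2 the number that fell was 9, and without siNC replicate 3 it was 14. MRPS18C fell by 0.68 (SE 0.08), MRPL20 by 0.42 (SE 0.06) and MRPL17 by 0.40 (SE 0.07). The nuclear subunits of complexes II to V had a median of -0.22 (camera adjusted p = 7.06e-07, and adjusted p = 0.383 with an estimated correlation, fry 0.0631), and 18 of 38 fell with 0 rising (24 and 0 adjusted over the list alone, and 11 to 21 fell with 1 library left out), among them UQCRB (-0.56), COX7A2 (-0.54) and COX7B (-0.50). Of 36 nuclear complex I subunits, 12 fell and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 0.000633, and adjusted p = 0.458 with an estimated correlation, fry 0.143). NDUFA12 fell by 0.46 and NDUFB3 by 0.45. Without siC1QBP replicate 1 the median of complex I went from -0.16 to -0.08, with 12 lower and 4 higher (camera adjusted p = 0.0334). That of complexes II to V went to -0.15, with 20 lower and 2 higher. The respiratory chain and mitochondrial ribosome genes together had a median transcript of 1256.5 bases and, without siC1QBP replicate 1, a median log2 fold change of -0.13.

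The 13 proteins encoded in mitochondrial DNA went the other way, with 11 rising and 0 falling (12 and 0 adjusted over the list alone) and a median of 0.27. The number rising was 7 without siNC replicate 2 or 3, and 1 fell without siC1QBP replicate 1. Camera gave an adjusted p of 3.92e-05, and adjusted p = 0.281 with an estimated correlation. MT-ND1 rose from 937 ± 28.0 to 1272 ± 83.2 CPM (SD, n = 3; log2 fold change 0.44, SE 0.05), and MT-ND4 and MT-ND2 both rose by 0.34 (SE 0.05 each). These genes lie within the mitochondrial share of counts that differed between the groups. Of 29 genes for mitochondrial biogenesis, import and dynamics, 5 fell, among them SLIRP and the import channel TOMM40 (-0.32), and 1 rose, the import receptor TOMM22 (0.30). Adjusted over the list alone, 7 fell and 3 rose, and the list was not called (camera adjusted p = 0.124). In the TCA cycle, 2 of 18 genes fell and 1 rose, citrate synthase CS (0.25, SE 0.04), with 4 and 1 adjusted over the list alone (camera adjusted p = 0.0742). The TCA list was called lower without siC1QBP replicate 1 (0.0158) or siNC replicate 1 (0.0397), with all genes that had at least 1 count (0.0188) and by camera on ranks (0.0473). With at least 1 count the biogenesis list was called lower too (0.0145).

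Glycolysis genes were lower (median -0.23; camera adjusted p = 2.51e-07, and adjusted p = 0.156 with an estimated correlation), and 12 of 23 fell with 0 rising; adjusted over the list alone, 17 fell and 1 rose. Hexokinase HK2 went from 62.2 ± 0.865 to 41.6 ± 0.671 CPM (SD, n = 3; log2 fold change -0.58, SE 0.06), the lactate exporter SLC16A3 fell by 0.51 (SE 0.05) and PGK1 by 0.31 (SE 0.04). Of 23 hypoxia response genes, 8 fell and 1 rose (4 to 8 falling with 1 library left out, 10 and 1 adjusted over the list alone, camera adjusted p = 0.00381, and adjusted p = 0.156 with an estimated correlation), with EGLN1 at -0.35 and the glucose transporter SLC2A1 at -0.25. Of 36 nucleolar and growth genes activated by MYC, 10 fell and 2 rose (7 to 15 falling with 1 library left out, 18 and 3 adjusted over the list alone, camera adjusted p = 0.000633, and adjusted p = 0.156 with an estimated correlation). RRS1 fell by 0.40 and LDHA by 0.26, while the nucleolar protein NOLC1 rose (0.66, SE 0.05).

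De novo purine synthesis, the pathway of PAICS, was not called (camera adjusted p = 0.569): 2 of 13 genes fell, PAICS and IMPDH1 (-0.20), and 0 rose, with 3 and 0 adjusted over the list alone. The IMPDH1 call was lost without siC1QBP replicate 2, siNC replicate 2 or siNC replicate 3 (edgeR adjusted p up to 0.127). Of 12 purine salvage and degradation genes, 3 fell and 2 rose, including xanthine dehydrogenase XDH (0.52, SE 0.11), with 4 and 3 adjusted over the list alone (camera adjusted p = 0.818). Pyrimidine and dNTP synthesis was lower (4 of 16 fell and 0 rose, the same counts adjusted over the list alone, camera adjusted p = 0.0132, and adjusted p = 0.186 with an estimated correlation). Thymidylate kinase DTYMK fell by 0.31 and thymidine kinase TK1 by 0.23, and the list was not called under a filter of at least 10 CPM (camera adjusted p = 0.0705). In one-carbon and serine metabolism 1 of 15 genes fell, SHMT1, and 0 rose, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.590). SHMT1 lost its call without any of 5 of the 6 libraries, siC1QBP replicate 1 excepted (edgeR adjusted p up to 0.126). It was also lost with DESeq2, library size only, and looser and stricter count filters.

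Cell cycle genes, with a median transcript of 3157 bases, were lower in both phases. Of 36 G2/M genes, 13 fell and 0 rose (11 to 21 falling with 1 library left out, 19 and 0 adjusted over the list alone, median -0.14, camera adjusted p = 5.21e-07, and adjusted p = 0.156 with an estimated correlation). The mitotic activator CDC20 fell by 0.33 (SE 0.05), CDK1 by 0.33 (SE 0.05) and ANLN by 0.29 (SE 0.04). Of 35 G1/S genes, 10 fell and 0 rose (4 falling without siNC replicate 2 and 6 without siNC replicate 3, 13 and 0 adjusted over the list alone, median -0.11, camera adjusted p = 5.69e-05, and adjusted p = 0.156 with an estimated correlation), with SLBP at -0.39, UHRF1 at -0.33 and the replicative helicase subunit MCM2 at -0.24. Among 16 CDK inhibitor and quiescence genes 2 fell, CDKN2C (-0.54) and CDKN2A (-0.41), and 1 rose, CDKN2B (0.37), with 3 and 2 adjusted over the list alone (camera adjusted p = 0.233). Of 25 p53 targets, 4 fell and 3 rose, the same counts adjusted over the list alone (camera adjusted p = 0.235), with PHLDA3 at -0.43 and SESN2 at 0.33. Of 31 apoptosis genes, 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.758), with BIRC3 at -0.32 among the falls.

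Targets of ATF4 in the integrated stress response were higher (9 of 32 rose and 2 fell, 13 and 2 adjusted over the list alone, camera adjusted p = 0.00769, and adjusted p = 0.236 with an estimated correlation). The cystine transporter SLC7A11 rose by 0.39 (SE 0.06) and TRIB3 by 0.32 (SE 0.05), while CEBPB fell by 0.36 (SE 0.05). The list was not called without siNC replicate 1 (camera adjusted p = 0.0643) or with all genes that had at least 1 count (0.0698). Cytosolic heat shock genes were lower (camera adjusted p = 0.00381, and adjusted p = 0.278 with an estimated correlation). Of 15, 4 fell and 0 rose (2 to 9 fell with 1 library left out, 9 and 0 adjusted over the list alone). HSPE1, the mitochondrial co-chaperonin, fell by 0.72 (SE 0.13), with 26.9, 45.5 and 46.8 CPM in siC1QBP replicates 1, 2 and 3. Its siNC libraries lay at 64.9 to 66.4 CPM. HSPB1 fell by 0.25 and DNAJB1 by 0.20, a call that DNAJB1 lost without siNC replicate 3 (edgeR adjusted p = 0.0562). No call was made for the ER unfolded protein response (4 fell and 0 rose of 20, 6 and 1 adjusted over the list alone, camera adjusted p = 0.233), where SDF2L1 fell by 0.53. Neither NRF2 targets (3 rose and 2 fell of 22, 9 and 4 adjusted over the list alone, adjusted p = 0.156) nor type I interferon genes (3 fell and 1 rose of 29, likewise adjusted over the list alone, adjusted p = 0.233), with IFIH1 at -0.54 and DDX60 at 0.35, were called (camera adjusted p). NF-kB and cytokine genes moved both ways, 8 rising and 5 falling of 27 (8 and 6 adjusted over the list alone, camera adjusted p = 0.527), with PTGS2 and SOD2 (0.37) higher and TNFAIP2 lower. In the complement system 4 of 12 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0661), with C1S at 0.57 and C1RL at 0.34. That list was called higher under a filter of at least 10 CPM (0.00319), with protein-coding genes only (just under the threshold) and without siNC replicate 2 (0.0410).

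Genes of the TGF-beta response and mesenchymal state were higher, 7 of 23 rising and 0 falling (9 and 0 adjusted over the list alone, camera adjusted p = 0.0141, and adjusted p = 0.186 with an estimated correlation). TGFBI rose from 952 ± 2.98 to 1207 ± 40.4 CPM (SD, n = 3; log2 fold change 0.34, SE 0.04), fibronectin FN1 by 0.26 and collagen COL1A1 by 0.43. The list was not called with all genes that had at least 1 count (camera adjusted p = 0.175). Focal adhesion and FAK signalling was not called (camera adjusted p = 0.838), with 3 of 33 rising and 2 falling (4 and 2 adjusted over the list alone), among them FN1 and the integrin ITGA2 (0.23, SE 0.05). Immediate early genes of ERK and serum signalling included FOS and EGR1 among 6 of 23 that rose, and the ERK phosphatase DUSP6 (-0.34) among 3 that fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.156). YAP/TAZ targets, 2 rising (CTGF, 0.46) and 4 falling (FJX1, -0.41) of 23, had the same counts adjusted over the list alone (camera adjusted p = 0.855). Epithelial junction genes rose in 3 and fell in 1 of 25 (4 and 4 adjusted over the list alone, camera adjusted p = 0.289), with CLDN1 at 0.32. Cholangiocyte genes rose in 5 and fell in 2 of 22 (7 and 4 adjusted over the list alone, camera adjusted p = 0.141), with MUC1 at 0.61, CFTR at 0.47 and keratin KRT7 at -0.26.

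Autophagy and lysosome genes were called higher (3 of 33 rose and 0 fell, 1 to 6 rose with 1 library left out, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0333, and adjusted p = 0.202 with an estimated correlation), with WIPI1 at 0.38. That call was lost without siC1QBP replicate 1 (camera adjusted p = 0.0517) or siNC replicate 1 (0.0596), 2 (0.0576) or 3 (0.0601), and with all genes that had at least 1 count (0.293). Replication-dependent histone genes were called higher (2 of 18 rose and 0 fell, 1 to 3 rose with 1 library left out, 5 and 0 adjusted over the list alone, camera adjusted p = 0.0343, and adjusted p = 0.236 with an estimated correlation), with HIST1H2BD at 0.61. That call was lost without siC1QBP replicate 2 (camera adjusted p = 0.0765), with library size as the only scaling (0.0619), and with a looser (0.128) or stricter (0.258) count filter. Splicing factors were lower (10 of 30 fell and 2 rose, 6 to 12 fell with 1 library left out, 15 and 3 adjusted over the list alone, camera adjusted p = 0.000633, and adjusted p = 0.156 with an estimated correlation), with SRSF9 at -0.40 and SRSF7 at -0.38. Lipid lists were not called in the main analysis: cholesterol synthesis (4 fell and 0 rose of 24, 8 and 1 adjusted over the list alone, camera adjusted p = 0.141, but called lower at 0.0240 with at least 1 count, HMGCS1 -0.19), fatty acid synthesis (3 rose and 1 fell of 17, 3 and 3 adjusted over the list alone, 0.233, SCD 0.22) and fatty acid oxidation (1 rose and 0 fell of 19, likewise adjusted over the list alone, 0.817, PPARA 0.29).

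With 1 library left out, the member counts of most uncalled lists moved as well, and their lowest and highest values follow. Falls ran from 0 to 3 in de novo purine synthesis, 0 to 4 in purine salvage, 0 to 2 in one-carbon metabolism, 3 to 10 in mitochondrial biogenesis, 0 to 3 in the TCA cycle and 3 to 6 in cholesterol synthesis. Rises ran from 1 to 2 in purine salvage, mitochondrial biogenesis, CDK inhibitors and YAP/TAZ targets, and from 2 to 4 in the complement system. In apoptosis 2 to 4 rose and 1 to 5 fell, in immediate early genes 3 to 5 and 1 to 4, in focal adhesion 2 to 4 and 0 to 4, and in NF-kB and cytokine genes 7 to 8 and 3 to 5. The NRF2 targets gave 1 to 3 and 0 to 2, type I interferon genes 1 to 2 and 1 to 3, epithelial junction genes 1 to 4 and 0 to 3, cholangiocyte genes 4 to 6 and 1 to 4, and fatty acid synthesis 1 to 3 and 0 to 3.

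Markers of other cell types were mostly under the count filter. Tested were 3 of 10 fibroblast, 3 of 10 leukocyte, 3 of 10 endothelial, 1 of 10 hepatocyte and 4 of 10 neuronal markers, too few for a list test. COL1A1 rose among the fibroblast markers. SERPINA1 (0.17), SNAP25 (0.58) and EGFL7 (-0.72) passed among the hepatocyte, neuronal and endothelial markers. Each of these lost its call when single libraries were left out: SERPINA1 without any siNC library (edgeR adjusted p up to 0.111), SNAP25 without any library but siNC replicate 3 (up to 0.216) and EGFL7 without any of the 6 (up to 0.179). DESeq2 also lost SNAP25 and EGFL7, limma-voom and library size only lost EGFL7, and leaving out mitochondrially encoded genes lost SNAP25. Leukocyte CD14 stood at 6.28 ± 0.392 against 6.39 ± 0.553 CPM (SD, n = 3; edgeR adjusted p = 0.933) and did not pass.

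**Figure D3:**
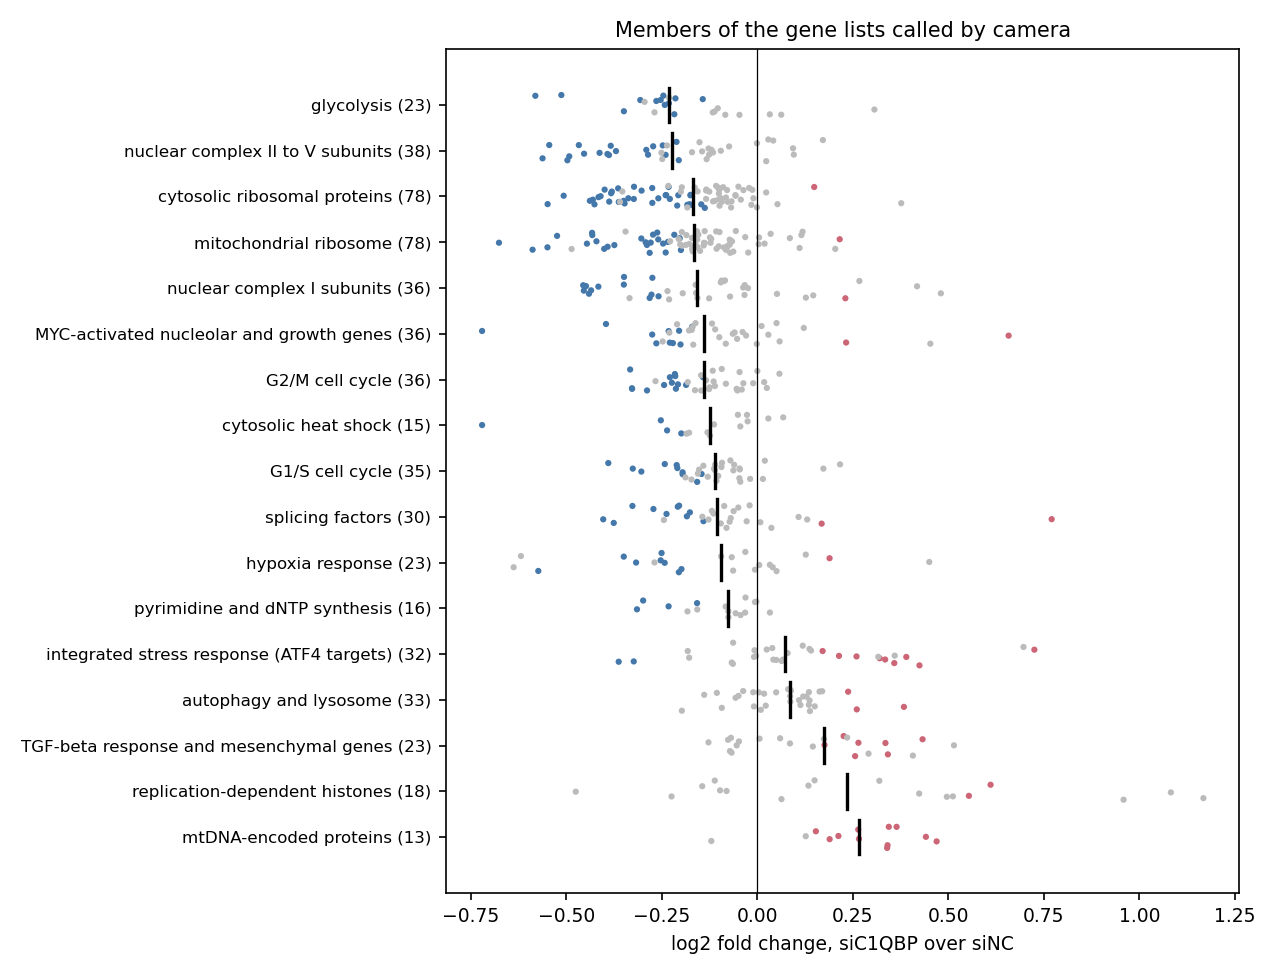
Log2 fold changes, siC1QBP over siNC (horizontal axis), of the tested members of the 17 lists that camera called with a preset correlation (vertical axis, tested members in brackets); red points rose, blue points fell, grey points did not pass, and black bars are medians. The medians run from -0.23 for glycolysis to 0.27 for proteins encoded in mitochondrial DNA, and 0 of these calls held with an estimated correlation.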

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

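The genomic DNA and nuclear RNA tests below were written before their results were seen, after the difference in detected genes had been noticed, except the 3 comparisons with an excess spread over all genes, which were chosen after. Genes left out of the test for low counts held 1875 ± 108 CPM in siC1QBP against 1449 ± 45.2 CPM in siNC libraries (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible), a signal above the control level in data outside the comparison. With it went more detected genes (25187 against 23614) and a higher share of lincRNA counts (0.495% against 0.433%). Of the antisense genes tested, 35 rose and 6 fell, assignments that are uncertain without a stated strand setting.

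Olfactory receptor genes were higher in each siC1QBP library than in each siNC library (exact permutation p = 0.1), as genomic DNA would need; the comparison set beforehand (an excess per kilobase 0.00158 times that of the antisense genes that rose) decides nothing, because those genes were picked for rising. Spread over all genes, that excess would give 0.111 (SE 0.0506) of the added counts in genes under the filter and 0.0134 (SE 0.00611) of the median excess per kilobase of all 812 tested antisense genes, which argues against genomic DNA as the main source of these, but 0.387 (SE 0.167) of the added detected genes, where it stays open. A higher share of nuclear RNA stays open too: nuclear noncoding RNAs lay 0.47 (SE 0.17) above cytosolic ones on the log2 scale, as that explanation predicts, but the nuclear median itself was 0.20 (SE 0.14), with 2 of 8 rising (NEAT1 and FTX); nuclear MALAT1, outside that set, held 0.0300% of counts against 0.0165% with no overlap between groups, which goes with it. The difference within the set came largely from cytosolic RNAs, 5 of 8 of which fell (GAS5, SNHG1, SNHG5, SNHG6 and ZFAS1), mostly snoRNA host genes that may move with the ribosomal protein mRNAs. An effect of C1QBP loss on these transcripts is the biological alternative and was not tested.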

How the results depend on the processing

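The larger side of the calls turned from lower (1005 higher, 1217 lower) to higher with library size only (1253 higher, 908 lower) and with at least 10 CPM in 3 libraries (1067 higher, 993 lower). The 17 called lists kept their direction in the alternatives run, and 7 uncalled lists did not in at least 1. In the alternatives fixed beforehand 0 of the named genes reversed. The called lists and most named genes were picked for passing in these same libraries, so reversals were unlikely and their absence says little. The C1QBP log2 fold change stayed between -1.64 and -1.56. Trend removal and thinning were the alternatives chosen after seeing the data. The count of 93 genes passing with at least 2-fold change became 20 with DESeq2, 152 with at least 1 count in any library, 7 with at least 10 CPM in 3 libraries and 60 with protein-coding genes only; the filters changed the genes tested, and the cause of the DESeq2 difference was not tested. At an adjusted p under 0.01, a stricter threshold by construction, 1057 genes passed (478 higher, 579 lower) and 33 of them changed at least 2-fold. Leaving out 1 library gave 1090 to 2607 genes (522 to 1134 higher, 568 to 1473 lower) and 51 to 108 at least 2-fold. Of the 1090 genes called without siNC replicate 2, 1072 were among the 2222. Camera with an estimated correlation called 0 lists against 17 (9 at an unadjusted p under 0.05, and fry called 24). The estimated correlation was 0.513 for cytosolic ribosomal proteins, but 0.00513 for glycolysis and -0.0292 for hypoxia, below the preset 0.01. For glycolysis the unadjusted camera p still went from 1.98e-08 to 0.00418. A higher correlation between genes therefore did not cause that loss. The run with an estimated correlation must differ from the preset run in another way too, which was not tested. Losing a call in it therefore does not by itself show that a list's genes move together. With the replicate number as a block, 3092 genes passed (1334 higher, 1758 lower). Libraries with the same number correlated at 0.04, 0.03 and -0.01 in their deviations from the group means, and those with different numbers at -0.05 to 0.02. All of these are small, and whether the numbers pair the samples stays open. Of 134 named genes besides C1QBP, 103 kept their call or lack of one in each alternative fixed beforehand that tested them at the same threshold (120 were tested with at least 10 CPM), and 116 of 1993 values kept their direction but no longer passed. At an adjusted p under 0.01, 105 of 131 called named genes passed. On thinned counts 2182 genes passed; genes under the count filter were too shallow to test.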

Other observations

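The gene families below were grouped by symbol after the data had been seen. The tests on the non-targeting duplex and on other splits of the libraries were also chosen after their results or the pattern had been seen, and trend removal was added after seeing the data. Among 165 families with at least 10 tested members, camera called 17 at the preset correlation and 0 with an estimated one. Zinc finger genes (ZNF) were higher, 35 rising and 6 falling of 381 (median 0.11; camera adjusted p = 0.000669, and adjusted p = 0.125 with an estimated correlation). Myosins (MYO) rose in 5 of 18 with 0 falling (camera adjusted p = 0.0246, and adjusted p = 0.648 with an estimated correlation). TIMM genes of mitochondrial import fell in 8 of 15 with 0 rising (camera adjusted p = 0.000576), LSM genes of RNA processing in 7 of 13 (0.00641), exosome EXOSC genes in 4 of 10 (0.00903) and proteasome PSMB genes in 5 of 10 (0.0296); each had an adjusted p = 0.648 with an estimated correlation.

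The real grouping called 2222 genes and the highest of the 9 other splits of the 6 libraries 0; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

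Ribosomal protein, nuclear-encoded mitochondrial and cell cycle mRNAs were lower, and the shortest transcripts fell most often. After each library's trend with length and GC content was removed, medians were -0.11 (SE 0.02) for ribosomal proteins, -0.15 (SE 0.02) for the nuclear respiratory chain and mitochondrial ribosome, and -0.13 (SE 0.02) for the cell cycle. All were still called by camera at the preset correlation, which argues against that trend as the whole cause. These SE are across genes and too small where genes move together (estimated correlation 0.513 for ribosomal proteins), so the strength of this argument is uncertain. Replicate 1 of siC1QBP as the only source is argued against for ribosomal proteins by a median of -0.11 without it, 65.9% of the value with all libraries. That median passes the bound set beforehand (-0.08) by little more than 1 SE across genes (0.02), so this is uncertain too. A response to C1QBP loss may explain these lists, but effects of the siRNA sequences and any unrecorded difference in how the arms were handled remain open. The labels name 1 siRNA per arm, and no list was called with an estimated correlation.

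Some of the most significant single changes may come from siRNA seed pairing in 3' UTRs, but of the 8 largest rises 0 hold a higher word below and 1 (NKD1) a lower one, and of the 7 largest falls after C1QBP 1 (SNRPB2) holds a lower one. The words tied to the highest fold changes were CGGAGAA and TCGGAGA (permutation p = 0.0099, the smallest that 100 permutations give). Of genes with either, 21.3% rose against 7.04% of those without. Of the 20, 50 and 100 most significant rises, 10, 17 and 22 held one against 0.875, 2.19 and 4.37 by the share of all searched genes. These raw shares are not adjusted for length, and rises were more frequent among long transcripts. AGGAGAA, which did not pass (permutation p = 0.366), also had more rises with it than without (10.7% against 6.58%). Besides CGGAGAA and TCGGAGA, the words GGAGAAA (permutation p = 0.0099), AAGGAGA and CGGAGAT (0.0198 each) passed. They are not whole within TCGGAGAA, the site formed by CGGAGAA and TCGGAGA. That site pairs with the first bases (TTCTCCGA) of the sense strand of a commonly sold non-targeting duplex (t = 6.42 for TCGGAGA). A candidate explanation is therefore release from repression present in siNC cells, but the sequence used here is not given in the labels. The words tied to the lowest fold changes after the regression, ATTATCC and TTATCCA (permutation p = 0.0099), form ATTATCCA in the coding part of C1QBP exon 4 of 6 (chromosome 17, 5433678 to 5433685, minus strand, hg38), as a C1QBP siRNA would need. But 6.86% of tested words occur in C1QBP, and words absent from it (TGGCGCA and GTGGCGC) also passed (permutation p = 0.0198 and 0.0297). Without the regression the direction turned for genes with either word. Their median log2 fold change was -0.008 against -0.021 for the others, 9.86% fell against 11.1%, and 8.79% rose against 7.45%. Of genes with the whole ATTATCCA, 12.6% fell and 7.08% rose, with a median of -0.045. Of the 20, 50 and 100 most significant falls, 5, 14 and 19 held a word against 3.18, 7.95 and 15.9 by share. The earlier scan on principal transcripts gave the same lower pair and put CGGAGAA and TCGGAGA at ranks 1 and 3 with GGAGAAA between them. Of the 10517 searched genes, 8502 hold none of ATTATCC, TTATCCA, CGGAGAA and TCGGAGA. Those 8502 held 578 of 806 rises and 968 of 1147 falls. That is a smaller share of the rises, and a larger share of the falls, than their share of the genes.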
